A study of Homo sapiens with 24 samples.

How the data were processed

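RNA of 24 libraries of the human fibroblast line Tig3 was sequenced, 3 libraries in each of 8 groups. Per the labels, RNA was taken up in Trizol and libraries were made with a TruSeq RNA kit from 1 ug of total RNA. The deposited values were whole-number read counts per gene, not normalized, in 1 table of 29574 genes with Ensembl identifiers, older gene symbols and GRCh37 coordinates. The submitters' processing notes name bcl2fastq 1.8.4, TopHat2 2.0.12, Bowtie and HTSeq, and GRCh37. Their roles and settings, and whether counting used strand, are not given in the sources used here, so counts of overlapping and antisense genes, like those of near-identical gene copies, are uncertain. The table held 24 count columns, each matched to a sample by its name, and 0 other columns of per-sample values. The titles give day 10 for the later harvest, while the column names and 1 label text give day 9. The text follows the titles. In the column names the 3 libraries of each group carry different dates, while the labels do not describe their cultures further. P-values measure the spread between these libraries of 1 cell line.

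Total counts per library were 9659268 to 16207733. No 2 replicates agreed within sampling noise: over genes with at least 10 counts in a pair, chi-square per degree of freedom was 11.13 to 161.83. Mean mitochondrial shares per group were 1.98% to 3.09%. Libraries were scaled with TMM and given as CPM. Principal components used log2 CPM with a prior count of 2.

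The main test was edgeR's quasi-likelihood test on the deposited counts, fitted with 1 term per group over all 24 libraries, which left 16 residual degrees of freedom. Genes were filtered with filterByExpr (minimum count 10, minimum total count 15), leaving 14210 genes, 12543 of them protein-coding. Adjusted p is by Benjamini-Hochberg over these genes, with a threshold of 0.05. There were 7 comparisons of groups and 2 tests of a difference between effects, the OIS effect at day 10 against that at day 4 and against the quiescence effect. SE is the absolute log2 fold change divided by the square root of F. For a gene at 0 counts in every library of a group, the fold is a lower bound with 3 counts per library in place of 0. For a group with 1 to 3 counts it is the ratio of CPM with a 95% interval. Such intervals and floors cover counting error only.

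The 23 gene lists were tested with limma's camera with a preset correlation of 0.01, with adjustment over 207 tests (23 lists in 9 contrasts), and again with a correlation estimated from the residuals. The lists, tests, alternatives and naming rule were fixed before the data were examined. The rule named, per comparison, the 5 higher and 5 lower genes with the largest change among those past the threshold, at 5 CPM or more in the higher group, with the same direction in all 3 same-numbered pairs and a named symbol. It added the 2 members with the smallest adjusted p of each list, and always BRAF, TERT, LMNB1, LMNA, LBR, CDKN1A, CDKN2A, CDKN2B, MKI67, CCNA2, IL6, IL8, IL1B, DUSP6 and HMGA1. For tests of a difference it took 4 genes each way without the rule on pairs. Some genes that the rule named are not reported here, though totals over the named genes include them where the processing was varied. Counts of shared calls were set beside the product of both list lengths over the genes tested, and beside 100 simulations of unchanged groups against the same control libraries where controls were shared.

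Replicate numbers come from the labels. In the column names, libraries with the same number share a date within a comparison, except bypass day 4 library 3, so the numbers pair the libraries. The correlations of the deviations of same-numbered libraries (numbers 1, 2 and 3) were 0.415, 0.204 and 0.028 for OIS and cycling cells at day 10 and -0.039, 0.054 and 0.144 at day 4. For bypass and cycling cells they were 0.554, 0.239 and 0.296 at day 10 and 0.108, 0.006 and 0.241 at day 4. For OIS and bypass cells they were 0.412, 0.28 and 0.26 at day 10 and 0.465, 0.339 and 0.386 at day 4, and for quiescent and serum cells -0.365, 0.21 and -0.439. The alternatives chosen beforehand were RLE size factors, no filter on low counts, DESeq2's Wald test, only the compared groups in the fit, the replicate number as a block, the library letter (A, B or C) in the column names as a covariate, the estimated correlation, and leaving out each library. After the data were seen, per-library offsets for GC content and transcript length and the setting aside of all libraries numbered 1 were added. Serum and quiescent libraries all have the letter C. GC content and length of the longest transcript came from GENCODE v29 by gene identifier, for 13900 tested genes (97.8%), and numbers of neighbouring protein-coding genes within 500 kb on each side were counted in that annotation.

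The scripts were tested on simulated counts drawn from the means of the real libraries over 14210 genes, with 50 genes changed at each fold. For OIS at day 10, 4% of 1.5-fold, 38% of 2-fold, 92% of 4-fold and 100% of 8-fold changes were recovered, and 6 of 127 calls were false. For quiescence these were 4%, 48%, 90% and 100%, with 5 of 126 calls false. None of 20 unchanged lists was called in either. The simulated genes were drawn independently, so this does not show how often lists of correlated genes are called falsely. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and Python 3.11.15 were used.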

Results

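RNA was sequenced and counted per gene in 24 libraries of Tig3 cells, a line of human diploid embryonic lung fibroblasts that carried the ecotropic receptor and the telomerase gene TERT. The 8 groups held 3 libraries each. Cells with an empty vector were the cycling cells, and cells given a constitutively active BRAF were the cells in oncogene-induced senescence (OIS). Cells that also carried the SV40 small T antigen when given BRAF were the bypass cells, in which the labels say that senescence was bypassed. Each of these was harvested 4 and 10 days after transduction, under selection with puromycin at 1 ug/ml. In a second experiment, cells were kept for 10 days in medium with 9% serum or with 0% serum, the latter called quiescent. Total counts per library ranged from 9659268 to 16207733. Levels are given as mean CPM (read counts scaled to library size with TMM) ± SD over the 3 libraries of a group (n = 3), coordinates are those of GRCh37, and adjusted p is from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the 14210 genes tested.

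The level of BRAF, the introduced oncogene (ENSG00000157764, chromosome 7, 140419127 to 140624564), was compared first because it checks the labels. It was 39.74 ± 3.88 CPM in cycling cells at day 4 and 28.84 ± 8.82 at day 10, against 1135 ± 324 and 1551 ± 823 in OIS cells and 974.7 ± 294 and 1818 ± 848 in bypass cells (n = 3 each). The log2 fold change in OIS at day 10 was 5.75 (SE 0.46, adjusted p = 2.04e-09), and every OIS and bypass library lay above every library of the other groups. OIS and bypass cells differed in BRAF by less than the spread between replicates at day 10 (log2 fold change -0.23, SE 0.38, adjusted p = 0.754) and at day 4 (0.22, SE 0.38, adjusted p = 0.822). Counts assigned to BRAF do not separate the vector's transcript from the cells' own. The small T antigen is not a human gene and was not measured here.

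**Figure D1:**
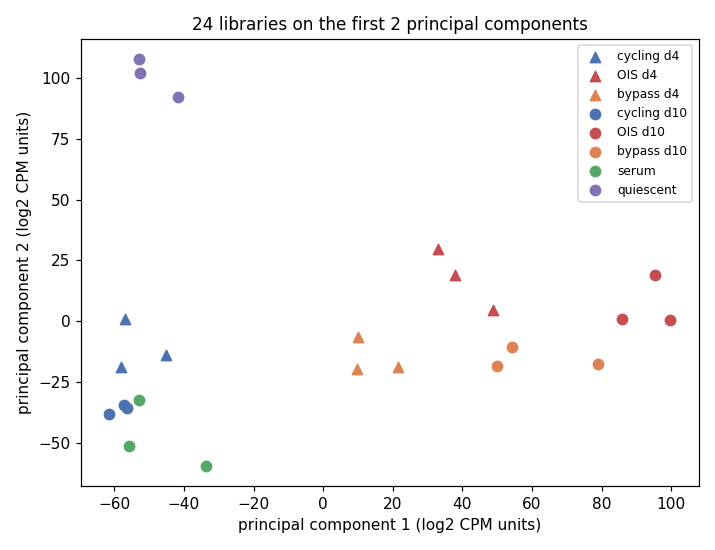
Scores of the 24 libraries on the first 2 principal components of log2 CPM (both axes in log2 CPM units), which hold 38.5% and 22.7% of the variance. Each point is a library (triangles, day 4), and the OIS libraries at day 10 lie highest on the first component, from 85.97 to 99.76, while the quiescent libraries lie highest on the second, from 91.97 to 107.7.

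The comparison of OIS with cycling cells at day 10 asks which genes change once senescence is induced. Genes of DNA replication and mitosis were lower in OIS, and secreted inflammatory factors, genes driven by the ERK kinase pathway and the CDK inhibitor genes CDKN2B, CDKN2A and CDKN1A were higher. MKI67, whose protein marks proliferating cells, fell from 195.7 ± 18.4 to 2.98 ± 1.51 CPM (log2 fold change -6.01, SE 0.58, adjusted p = 2.86e-08). IL1B, an inflammatory cytokine, rose from 1.91 ± 0.986 to 6340 ± 1060 CPM (log2 fold change 11.65, SE 0.81, adjusted p = 2.82e-10). LMNB1, the gene of lamin B1 in the nuclear lamina (ENSG00000113368, chromosome 5, 126112315 to 126172712), fell from 56.39 ± 15.8 to 4.65 ± 0.442 CPM (log2 fold change -3.59, SE 0.26, adjusted p = 4.85e-10). In all, 5666 genes changed, 3031 higher and 2635 lower, and 3676 of them changed at least 2-fold. The majority turned with GC and length offsets (3487 higher, 3611 lower) and without OIS day 10 library 1 (2495 and 2649) or 2 (2872 and 2923) or cycling day 10 library 2 (2335 and 2408) or 3 (2353 and 2510).

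Of the 51 measured genes of DNA replication and G1/S, 49 fell and none rose (50 fell when adjusted over the list alone). The list was called lower than other genes (median log2 fold change -2.1, camera adjusted p = 5.24e-32, and 0.0101 with an estimated correlation). TK1, a thymidine kinase of the S phase, fell from 83.39 ± 24.8 to 1.68 ± 0.315 CPM, and ORC1, a subunit of the origin recognition complex, from 12.43 ± 1.84 to 1.17 ± 0.141. Of the 63 genes of G2/M and mitosis, 62 fell, also when adjusted over the list alone (median -4.69, camera adjusted p = 9.47e-57, and 0.00471 with an estimated correlation). They included CCNA2 (cyclin A2), from 68.9 ± 1.09 to 2.24 ± 0.775 CPM, and the transcription factor gene MYBL2, from 37.06 ± 9.76 to 0.954 ± 0.223. The 11 CDK inhibitor and RB family genes were not called as a list (4 rose, 3 fell, 5 and 3 when adjusted over the list alone, camera adjusted p = 0.746, median -0.01, mean 0.04). Among them CDKN2B rose from 13.27 ± 3.62 to 510.2 ± 165 CPM (log2 fold change 5.26, SE 0.3), CDKN2A from 18.06 ± 3.34 to 100.3 ± 24.9 (2.47, SE 0.28) and CDKN1A from 659.7 ± 94.4 to 2774 ± 867 (2.07, SE 0.29). CDKN3, a phosphatase gene in the same list, fell from 13.42 ± 2.65 to 0.448 ± 0.224.

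Of the 66 measured genes of the senescence-associated secretory phenotype (SASP), 46 rose and 6 fell (51 and 7 when adjusted over the list alone). The list was called higher (median log2 fold change 2.73, camera adjusted p = 1.18e-18, and 0.00972 with an estimated correlation). IL8, the gene of the chemokine interleukin-8, rose from 0.514 ± 0.175 to 1093 ± 418 CPM, STC1, the secreted stanniocalcin 1, from 83.63 ± 16.9 to 5455 ± 1730, and BMP2, a growth factor, from 0.101 ± 0.0386 to 167.5 ± 34.9. IL6 rose less, from 1.36 ± 0.352 to 12.21 ± 4.06 CPM (log2 fold change 3.13, SE 0.77, adjusted p = 0.0022). Of the 27 genes driven by the ERK pathway, 19 rose and 2 fell (20 and 3 when adjusted over the list alone, median 2.25, camera adjusted p = 2.87e-10, and 0.0336 with an estimated correlation). DUSP6, a phosphatase that acts on ERK, rose from 15.88 ± 2.7 to 751.9 ± 88.7 CPM. Of the 35 p53 target genes, 21 rose and 1 fell (23 and 1 when adjusted over the list alone, median 0.74, camera adjusted p = 2.56e-05, and 0.0377 with an estimated correlation), with GDF15 at 374.7 ± 113 CPM against 8.07 ± 2.1. Of the 23 NF-kB targets, 12 rose and none fell (14 when adjusted over the list alone, camera adjusted p = 0.000389). That call was lost with an estimated correlation (adjusted p = 0.155).

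Genes of the contractile and matrix programme of fibroblasts were lower. Of the 27 contractile genes, 23 fell, also when adjusted over the list alone (median log2 fold change -1.76, camera adjusted p = 3.07e-17, and 0.0144 with an estimated correlation). CYR61, a matricellular protein gene, fell from 597.1 ± 130 to 13.04 ± 6.75 CPM, and FLNC (filamin C) from 1297 ± 152 to 164.2 ± 27.5. Of the 49 extracellular matrix genes, 30 fell and 6 rose (32 and 6 when adjusted over the list alone, median -1.18, camera adjusted p = 2.2e-07), a call lost with an estimated correlation (adjusted p = 0.322). COL1A2, a chain of collagen I, fell from 6338 ± 982 to 1160 ± 44.6 CPM. Of the 31 genes of the nuclear lamina and envelope, 12 fell and 1 rose, the same when adjusted over the list alone, and the list was not called (median -0.36, camera adjusted p = 0.0559). It was called with no filter on low counts (adjusted p = 0.00372) and without cycling day 10 library 2 (0.0394), OIS day 10 library 2 (0.0478) or library 3 (0.0415). Besides LMNB1, LMNA (lamins A and C) fell from 1056 ± 121 to 519.3 ± 162 CPM (log2 fold change -1.02, SE 0.23, adjusted p = 0.00117) and LBR (lamin B receptor) from 48.78 ± 6.96 to 18.95 ± 4.63 (-1.36, SE 0.24, adjusted p = 7.05e-05). The 46 heterochromatin genes went both ways (11 rose, 13 fell, 11 and 15 when adjusted over the list alone, camera adjusted p = 0.449). HMGB2, a chromatin protein gene, fell from 84.42 ± 15 to 16.89 ± 2.44 CPM, and HMGA1, a gene of senescence-associated heterochromatin foci, was at 1058 ± 227 against 846.5 ± 169 CPM (adjusted p = 0.456).

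The genes with the largest changes included CSF3, a colony-stimulating factor, listed at 0 counts in the 3 cycling libraries and at 81.42 ± 28.4 CPM in OIS, at least 348-fold higher with 3 counts per library as the floor. TREM1, a receptor of myeloid cells, and DCSTAMP, a fusion protein of osteoclasts, were also at 0 counts in cycling cells, TREM1 at least 233-fold and DCSTAMP at least 150-fold higher in OIS. CXCR4, a chemokine receptor, had 2 counts in all cycling libraries together and a count ratio of 3890 (95% counting interval 1080 to 32200). The tight junction gene CLDN11 fell from 321.5 ± 66.3 to 2.87 ± 0.56 CPM, the oxytocin receptor gene OXTR from 124.7 ± 42.9 to 0.571 ± 0.455 and ENPP2 (autotaxin) from 36.65 ± 10.3 to 0.304 ± 0.141.

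Among the other lists, lysosome genes (15 rose, 3 fell of 44, the same when adjusted over the list alone) and genes of FOXO activity and quiescence (16 rose, 2 fell of 33, 18 and 3 when adjusted over the list alone) were called higher, and glycolysis genes (11 fell, 2 rose of 24, the same when adjusted over the list alone) lower. None of these 3 calls held with an estimated correlation (adjusted p = 0.609, 0.276 and 0.677). The glycolysis call was lost with the library letter as a covariate (adjusted p = 0.064) and without cycling day 10 library 1 (adjusted p = 0.0713) or OIS day 10 library 2 (0.111), and the lysosome call with offsets for GC content and length (0.0527). The cathepsin gene CTSS rose from 0.802 ± 0.163 to 35.83 ± 9.17 CPM, and SLC2A1, a glucose transporter, fell from 276.7 ± 4.92 to 89.01 ± 4.58. Lists of interferon response (5 rose, 7 fell of 28), cholesterol synthesis (1 rose, 6 fell of 29), ribosome biogenesis (5 rose, 5 fell of 49), unfolded protein stress (4 rose, 8 fell of 26) and heat shock genes (3 rose, 1 fell of 13) were not called, with camera adjusted p of 0.949, 0.449, 0.459, 0.505 and 0.927. Over the list alone these counts were 5 and 7, 1 and 3, 0 and 2, 4 and 8, and 3 and 1.

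Markers of other cell types were measured beside these groups. Of the 7 endothelial genes, 5 rose and 2 fell, the same when adjusted over the list alone (median log2 fold change 1.74, camera adjusted p = 0.0208, and 0.134 with an estimated correlation). They included TIE1, an endothelial receptor, from 1.57 ± 0.584 to 74.71 ± 9.37 CPM, and VWF from 0.421 ± 0.0588 to 5.54 ± 0.52, while ENG (endoglin), the most abundant gene of that list and chosen here after its values were seen, fell from 397.8 ± 49.8 to 155.7 ± 46. Epithelial (1 rose, 2 fell of 5), blood cell (1 rose, 1 fell of 3) and neural (5 rose, 4 fell of 15) genes were not called (camera adjusted p = 0.746, 0.927 and 0.74). Over the list alone their counts were 1 and 2, 2 and 1, and 6 and 4. The median and mean differed in sign for interferon (0.19 and -0.16), epithelial (0.56 and -0.47) and blood cell genes (1.39 and -0.41), with camera's direction lower, lower and higher. With TMM scaling over all genes in the table, tested or not, blood cell and epithelial markers were at low levels in OIS at day 10. The highest mean over the 14 blood cell genes in the table was 2.65 CPM (CSF1R), and over the 17 epithelial genes 11.8 CPM (KRT18). Endothelial and neural lists held genes at higher levels, up to 155.14 CPM (ENG) over 12 endothelial and 60.6 CPM (NEFM) over 27 neural genes. The share of mitochondrial counts was 2.29% ± 0.72 in OIS and 1.98% ± 0.2 in cycling cells (n = 3).

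**Figure D2:**
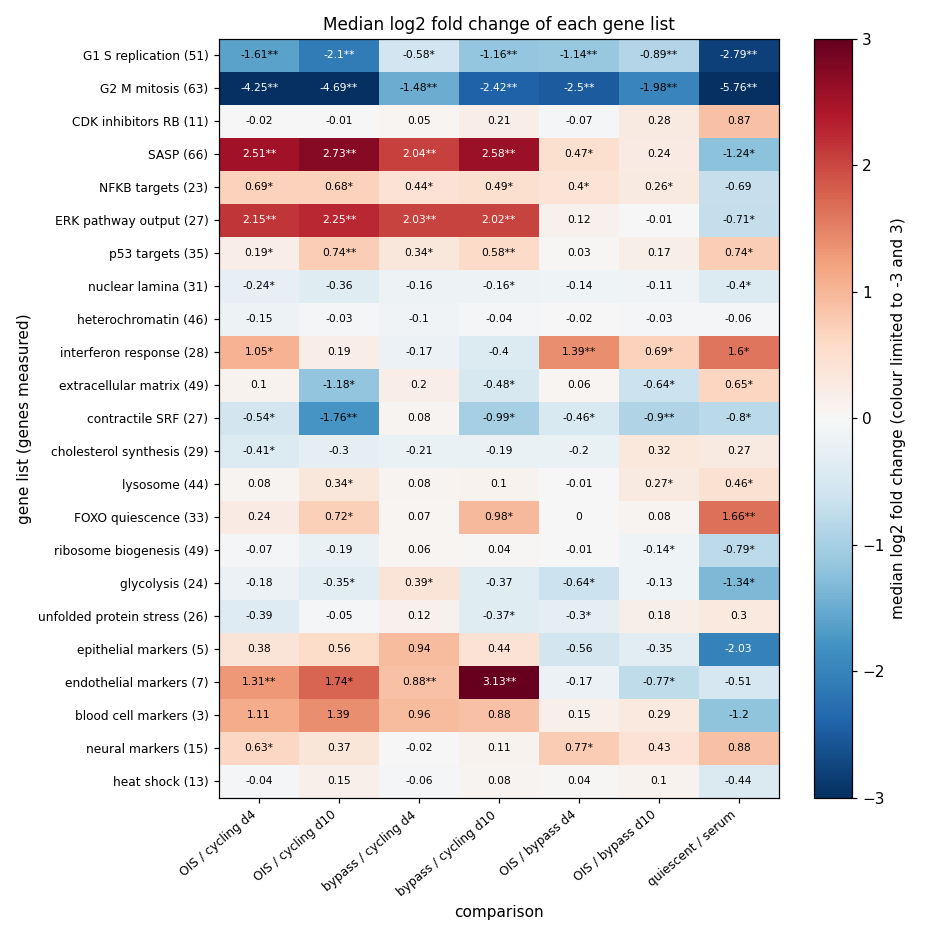
Median log2 fold change (colour and printed value) of the measured genes of each fixed list (vertical axis, number of genes in parentheses) in the 7 comparisons (horizontal axis). 1 star marks a list called by camera with the preset correlation only and 2 stars a list called also with an estimated correlation, as for G2/M and mitosis genes in all 7 comparisons.

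The same comparison at day 4 asks which changes were present earlier. Cell cycle genes were already low, and SASP and ERK pathway genes already high, in OIS cells at day 4. MKI67 fell from 163.3 ± 43.3 to 1.82 ± 0.871 CPM (log2 fold change -6.46, SE 0.61, adjusted p = 4.46e-08), and STC1 rose from 97.16 ± 24.8 to 10330 ± 527 CPM (6.73, SE 0.34, adjusted p = 9.16e-12). LMNB1 fell from 38.03 ± 11.9 to 8 ± 0.358 CPM (log2 fold change -2.25, SE 0.24, adjusted p = 3.06e-07), while CDKN1A was at 1254 ± 170 against 954.6 ± 242 (adjusted p = 0.35). In all, 2912 genes changed, 1706 higher and 1206 lower. With offsets for GC content and transcript length 4424 genes changed, and the share of higher calls went from 58.6% to 48.1% (2130 higher).

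At day 4, 45 of the 51 replication genes fell (47 when adjusted over the list alone, median log2 fold change -1.61, camera adjusted p = 6.16e-39) and 59 of the 63 mitosis genes (61 when adjusted over the list alone, median -4.25, camera adjusted p = 5.6e-86). Both calls held with an estimated correlation (adjusted p = 0.00687 and 0.00316). ASPM, a spindle gene, fell from 64.88 ± 17.4 to 0.912 ± 0.825 CPM. Of the SASP genes, 44 rose and 2 fell (45 and 4 when adjusted over the list alone), and of the ERK pathway genes 22 rose and 1 fell, also when adjusted over the list alone. Their medians were 2.51 and 2.15, and both calls held with an estimated correlation (adjusted p = 0.00351 for each). IL8 rose from 1.31 ± 0.765 to 197.3 ± 46.9 CPM, IL1B from 1.5 ± 0.507 to 476.8 ± 212, IL6 from 2.39 ± 1.43 to 29.39 ± 12.8, and DUSP6 from 22.62 ± 9.18 to 888 ± 109. Of the 28 interferon response genes, 15 rose and none fell (16 when adjusted over the list alone, median 1.05, camera adjusted p = 1.19e-05, and 0.0596 with an estimated correlation). ISG20 rose from 2.59 ± 0.438 to 70.79 ± 17.3 CPM and OAS1 from 0.212 ± 0.0651 to 3.26 ± 0.675.

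CDKN2B rose from 24.23 ± 6.49 to 242.1 ± 12.5 CPM and CDKN2A from 14.36 ± 1.89 to 49.95 ± 7.38 at day 4. LMNA fell from 844.2 ± 142 to 459.4 ± 78.6 CPM and LBR from 55.56 ± 1.71 to 26.05 ± 6.13. HMGA1 rose from 602.2 ± 24.3 to 1483 ± 384 CPM (log2 fold change 1.3, SE 0.33, adjusted p = 0.00587). The endothelial genes were called higher also with an estimated correlation (3 of 7 rose, also over the list alone, camera adjusted p = 0.000536 and 0.0324), with TIE1 at 100.3 ± 5.89 CPM against 1.44 ± 0.0807. Calls for NF-kB targets (11 of 23 rose), p53 targets (8 of 35 rose), nuclear lamina (5 of 31 fell), contractile (9 of 27 fell), cholesterol synthesis (4 of 29 fell) and neural genes (6 of 15 rose) were lost with an estimated correlation, with adjusted p of 0.123, 0.229, 0.0958, 0.484, 0.819 and 0.304. Of the nuclear lamina genes 1 rose. The cholesterol synthesis call was also lost with the library letter as a covariate (0.0544) and without cycling day 4 library 1 (0.0925), library 3 (0.0924) or OIS day 4 library 3 (0.13). The neural call was lost without OIS day 4 library 2 (0.0642) or library 3 (0.05). ANO3, an anoctamin gene, was at 0 counts in cycling cells and 24.67 ± 11.3 CPM in OIS, at least 116-fold higher. AREG, a ligand of the EGF receptor whose count is uncertain because of a near-identical copy, had 1 count in the cycling libraries and a count ratio of 1900 (95% counting interval 340 to 75000).

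A test of the difference between both OIS effects asks whether the effect at day 10 differs from that at day 4. Matrix and contractile genes were lower at day 10 relative to day 4, beyond what the cycling cells showed. Of the 27 contractile genes, 16 had a lower effect at day 10 (21 when adjusted over the list alone, median difference -1.33, camera adjusted p = 4.92e-24, and 0.00545 with an estimated correlation), and of the 49 matrix genes 20 (25 when adjusted over the list alone, median -1.29, camera adjusted p = 7.02e-23, and 0.0415 with an estimated correlation). COL1A2 fell by 2.45 on the log2 scale at day 10, and its difference between the days was -2.49 (adjusted p = 3.87e-05). Among genes with lower effects at day 10 was ABI3BP, a matrix protein gene that was at 0.548 ± 0.408 CPM in OIS at day 10 and 74.77 ± 20 at day 4 (difference -7.11, SE 0.64, adjusted p = 5.44e-07). CDKN1A and CDKN2B had larger effects at day 10 (differences 1.68 and 1.94, adjusted p = 0.00993 and 0.0017). From day 4 to day 10, mean CDKN1A went from 1254 to 2774 CPM in OIS and from 954.6 to 659.7 in cycling cells. Mean CDKN2B went from 242.1 to 510.2 CPM in OIS and from 24.23 to 13.27 in cycling cells. Part of both differences thus lies in the cycling cells. In all, 1037 genes differed, 377 higher and 660 lower at day 10. With GC and length offsets the count was 2281, and without cycling day 4 library 2 it was 632. Of genes called in either direction in the effects at both days, 1261 rose in both, 933 fell in both and 43 moved in opposite directions, against 363.9, 223.6 and 573.6 from independent lists of these sizes. These 2 effects share no library.

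**Figure D3:**
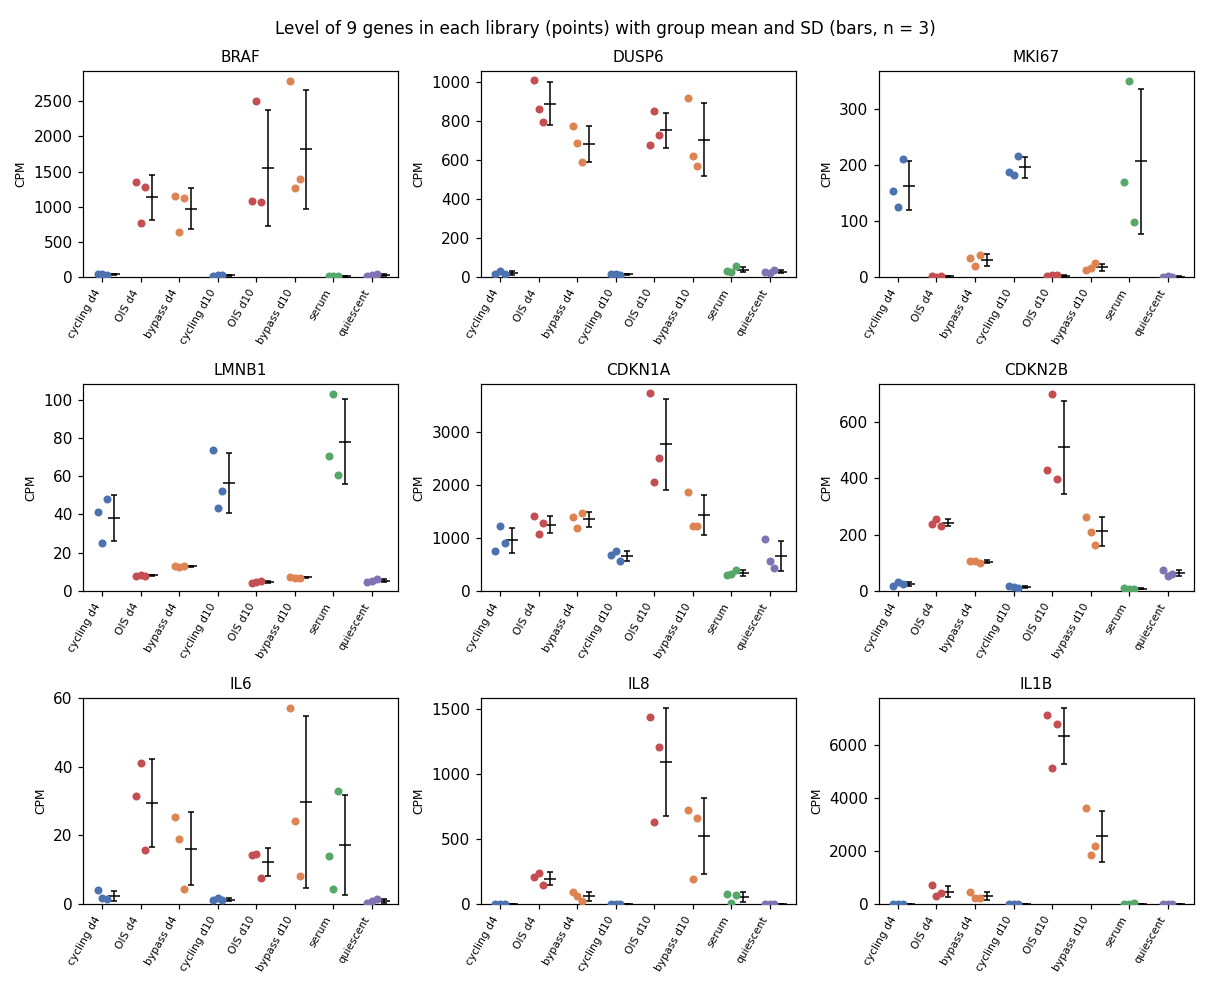
CPM (vertical axis, linear, from 0) of 9 genes in each of the 24 libraries (points, by group along the horizontal axis), with the mean and SD of each group of 3 (bars). BRAF and DUSP6 are high in all OIS and bypass libraries, MKI67 and LMNB1 are high in cycling and serum libraries, and IL1B is highest in OIS at day 10 (6340 ± 1060 CPM).

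The bypass cells were compared with cycling cells to ask what BRAF does where small T antigen is also present. No library with small T antigen alone was analysed here, so the effects of BRAF and of small T antigen cannot be separated in this comparison. Lists of SASP and ERK pathway genes were called higher and of mitosis genes lower in bypass cells at both days. Replication genes were called lower at both days, at day 4 with 22 of 51 past the threshold and a call lost with an estimated correlation (adjusted p = 0.229). At day 10, IL1B was at 2549 ± 946 CPM in bypass and 1.91 ± 0.986 in cycling cells (log2 fold change 10.34, SE 0.77, adjusted p = 1.73e-09), and MKI67 at 17.62 ± 6.56 against 195.7 ± 18.4 (-3.47, SE 0.51, adjusted p = 1.67e-05). LMNB1 fell to 7 ± 0.36 CPM (-3.01, SE 0.25, adjusted p = 7.69e-09) and LMNA to 342.9 ± 29.3 (-1.62, SE 0.24, adjusted p = 1.59e-05). In all, 4074 genes changed at day 10, 2162 higher and 1912 lower. The majority turned with GC and length offsets (2566 higher, 3053 lower) and without cycling day 10 library 3 (1624 and 1665).

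Of the SASP genes, 48 rose and 5 fell in bypass cells at day 10 (50 and 7 when adjusted over the list alone, median log2 fold change 2.58, camera adjusted p = 5.65e-26), and of the ERK pathway genes 21 rose and 2 fell (22 and 2 over the list alone, median 2.02, camera adjusted p = 1.32e-18). Of the p53 targets, 17 rose (median 0.58, camera adjusted p = 1.57e-05). These calls held with an estimated correlation (adjusted p = 0.00471, 0.0056 and 0.0377). STC1 was at 4618 ± 1180 CPM, and TNFSF15, a member of the TNF family, at 816.6 ± 161 against 0.439 ± 0.211 in cycling cells. LCE1F, of the late cornified envelope family, was at 282.2 ± 110 CPM, a count ratio of 3630 (95% counting interval 1240 to 17600); reads of near-identical family members make its count uncertain. Among replication genes 41 of 51 fell (42 over the list alone, median -1.16, and 0.0377 with an estimated correlation) and among mitosis genes 54 of 63 (58 over the list alone, median -2.42, adjusted p = 0.0106 with an estimated correlation). CDKN2B rose to 210.8 ± 50 CPM, CDKN2A to 48.41 ± 9.81 and CDKN1A to 1441 ± 378, while CDKN2C, another CDK inhibitor gene, fell from 21.78 ± 3.74 to 1.56 ± 0.561. Of the 7 endothelial genes 5 rose and 1 fell (camera adjusted p = 6.35e-06, and 0.00833 with an estimated correlation), with TIE1 at 127.8 ± 28.8 CPM.

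Other list calls in bypass cells at day 10 were lost with an estimated correlation, with its adjusted p given after each count. They were higher NF-kB targets (10 of 23 rose, adjusted p = 0.23) and FOXO genes (20 of 33 rose, 0.158), and lower contractile (17 of 27 fell, 0.0958), matrix (16 of 49 fell, 0.677), unfolded protein stress (8 of 26 fell, 0.564) and nuclear lamina genes (6 of 31 fell, 0.134). Against these directions, 1 NF-kB target and 3 FOXO genes fell, and 7 matrix, 3 unfolded protein stress and 1 nuclear lamina gene rose. The lamina call was also lost with the replicate number as a block (adjusted p = 0.0514), with only the compared groups in the fit (0.0594), with all libraries numbered 1 set aside (0.0502) and without bypass day 10 library 2 (0.0716). The unfolded protein stress call was lost with GC and length offsets (0.0865) and without bypass day 10 library 2 (0.16) or cycling day 10 library 3 (0.0601). ELN, the elastin gene, fell from 140.3 ± 42.3 to 9.01 ± 4.18 CPM, and the chemokine gene CXCL12 from 105.4 ± 23.9 to 2.26 ± 0.876.

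At day 4, bypass cells differed from cycling cells in 2730 genes, 1505 higher and 1225 lower. The majority turned with only the compared groups in the fit (2233 higher, 2789 lower), no filter on low counts (1476 and 1740), GC and length offsets (1674 and 1871), the replicate number as a block (1854 and 1907) and the library letter as a covariate (1915 and 1929). STC1 was at 4987 ± 409 CPM, TIMP1, an inhibitor of metalloproteinases, at 4274 ± 826 against 297 ± 15.7, and DUSP6 at 682.5 ± 90.7. Of the SASP genes 40 rose and 1 fell, and of the ERK pathway genes 21 rose and none fell (46 and 3, and 22, over the list alone). Both calls held with an estimated correlation (adjusted p = 0.00351 and 0.00316). Among mitosis genes 45 of 63 fell (53 over the list alone, median -1.48, and 0.0489 with an estimated correlation), with ASPM at 5.22 ± 1.7 CPM, and among replication genes 22 of 51 (24 over the list alone, median -0.58). LMNB1 fell to 12.84 ± 0.327 CPM, and HMGA1 rose to 2102 ± 523. The endothelial call held (4 of 7 rose, adjusted p = 0.00833 with an estimated correlation), while those of NF-kB targets, p53 targets and glycolysis genes did not (adjusted p = 0.39, 0.247 and 0.66). The NF-kB call was also lost without bypass day 4 library 2 (0.0908), and the glycolysis call without cycling day 4 library 1 (0.0816), library 2 (0.128) or bypass day 4 library 3 (0.0754). Both were lost with GC and length offsets (0.156 and 0.192). The library letter as a covariate also ended the glycolysis call (0.0629). The 28 interferon genes were not called (2 rose, 8 fell, camera adjusted p = 0.0869), but were called lower without cycling day 4 library 2 (adjusted p = 0.0399) or bypass day 4 library 2 (0.0312). The count of changed genes was 5022 with only the compared groups in the fit, and 1340, 1702 and 1803 without bypass day 4 library 1, library 3 or cycling day 4 library 2.

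Most calls of the OIS and bypass effects at day 10 went the same way. Genes higher in both numbered 1812, genes lower in both 1503, and 9 moved in opposite directions, against 461.2, 354.5 and 808.7 from independent lists of these sizes. Across genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.895 and a covariance of 1.918. Both effects were measured against the same cycling libraries, and 100 simulations of unchanged groups against them gave a mean correlation of 0.508, a covariance of 0.0852 (observed minus simulated, 1.833) and 0 shared calls. The highest simulated covariance was 0.0927, far below 1.918, which argues against the shared controls as the source of most of it. No gene was changed in the simulations, so hardly any shared calls could arise there, and the 0 does not bear on the observed ones. Simulated counts were fitted for the day 10 cycling, OIS and bypass libraries alone, and the observed ones with all 24 libraries. The simulated libraries were also drawn independently, whereas deviations of same-numbered OIS and bypass libraries correlated at 0.412, 0.28 and 0.26. The 3 cycling libraries also cannot be split with 2 in each part. Part of the excess may thus still come from libraries that share a number or from the controls.

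OIS and bypass cells at day 10 were compared directly to ask how cells given BRAF alone differ from cells given BRAF with small T antigen, in which the labels say that senescence was bypassed. Cell cycle, contractile and some matrix genes were lower in OIS than in bypass cells, while BRAF, DUSP6 and the SASP list as a whole did not pass the test. CCNA2 was at 2.24 ± 0.775 CPM in OIS and 6.85 ± 1.82 in bypass cells (log2 fold change -1.6, SE 0.28, adjusted p = 0.000582), and MKI67 at 2.98 ± 1.51 against 17.62 ± 6.56 (-2.54, SE 0.52, adjusted p = 0.00282). CDKN2B was higher in OIS, at 510.2 ± 165 against 210.8 ± 50 (1.28, SE 0.25, adjusted p = 0.00198). The cytokine gene IL24 was at 38.72 ± 18.7 CPM against 3.07 ± 0.595 (3.66, SE 0.43, adjusted p = 2e-05). In all, 1524 genes differed, 646 higher and 878 lower in OIS.

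Replication genes (24 of 51 lower, 31 over the list alone, median -0.89), mitosis genes (50 of 63 lower, 57 over the list alone, median -1.98) and contractile genes (14 of 27 lower, 17 over the list alone, median -0.9) were called, also with an estimated correlation (adjusted p = 0.0404, 0.0106 and 0.0208). CYR61 was at 13.04 ± 6.75 CPM in OIS and 143 ± 45.3 in bypass, and CNN1 (calponin 1) at 0.818 ± 0.326 against 6.7 ± 0.721. Of the 49 matrix genes 15 were lower (21 over the list alone), with THBS1 (thrombospondin 1) at 473.7 ± 248 against 3092 ± 1040, a list call lost with an estimated correlation (adjusted p = 0.229). Of the SASP genes, 4 were higher and 8 lower (the same over the list alone, camera adjusted p = 0.317). The list was called higher without bypass day 10 library 1 (adjusted p = 0.0407) and with all libraries numbered 1 set aside (0.0173). IL1B was at 6340 ± 1060 against 2549 ± 946 CPM (log2 fold change 1.31, SE 0.51, adjusted p = 0.105), IL6 at 12.21 ± 4.06 against 29.82 ± 25 (adjusted p = 0.223) and DUSP6 at 751.9 ± 88.7 against 703.4 ± 186 (adjusted p = 0.869). IL1B was called with the replicate number as a block (0.0151), with only the compared groups in the fit (0.0444) and with no filter on low counts (7.4e-06), which also called IL6 (0.000134) and IL8 (0.00107, and 0.245 with the filter). MYC, in the ERK list, was lower in OIS, at 36.8 ± 9.68 against 109.8 ± 12 CPM. Lamin genes did not pass the test, with LMNB1 at 4.65 ± 0.442 against 7 ± 0.36 (adjusted p = 0.14) and LMNA at 519.3 ± 162 against 342.9 ± 29.3 (0.102, called without OIS day 10 library 2 at 0.0213 and with GC and length offsets at 0.0446).

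CDKN2A (100.3 ± 24.9 against 48.41 ± 9.81 CPM, adjusted p = 0.0122) lost its call without OIS day 10 library 1 (0.0993) or bypass day 10 library 3 (0.0989), and with only the compared groups in the fit (0.0546). CDKN1A (2774 ± 867 against 1441 ± 378, adjusted p = 0.031) lost it without OIS day 10 library 1 (0.23), library 3 (0.0539), bypass day 10 library 2 (0.151) or library 3 (0.154), and with only the compared groups (0.115). Of the 28 interferon genes, 6 were higher and 1 lower (10 and 3 over the list alone, median 0.69), a call lost with an estimated correlation (adjusted p = 0.366), with all libraries numbered 1 set aside (0.0866) and without bypass day 10 library 1 (0.0643) or OIS day 10 library 3 (0.0563). Calls of NF-kB targets, lysosome and ribosome biogenesis genes, with medians of 0.26, 0.27 and -0.14, were lost with an estimated correlation (adjusted p = 0.419, 0.643 and 0.613), as was that of the 7 endothelial genes (3 lower, median -0.77, adjusted p = 0.123). Leaving out OIS day 10 library 1 ended the NF-kB (0.0644), lysosome (0.0514) and endothelial (0.124) calls, and library 2 those of NF-kB (0.0748), lysosome (0.071), ribosome biogenesis (0.526) and endothelial genes (0.0597). Leaving out OIS day 10 library 3 ended the endothelial call (0.148), as did bypass day 10 library 1 (0.165) or 2 (0.0763). Bypass day 10 library 2 also ended the NF-kB call (0.118), and library 3 those of lysosome (0.168) and ribosome biogenesis genes (0.145). With the replicate number as a block the ribosome biogenesis (0.0546) and endothelial (0.0862) calls ended. The ribosome biogenesis call ended also with the library letter as a covariate (0.0524) and, like that of NF-kB targets, with only the compared groups in the fit (0.0712 and 0.0696). The NF-kB call ended with GC and length offsets (0.0652), and the endothelial call with no filter on low counts (0.151) and with all libraries numbered 1 set aside (0.297). The count of genes was 529 with only the compared groups in the fit, 2520 with GC and length offsets, 794 and 2449 without OIS day 10 library 1 or 2, and 801 and 781 without bypass day 10 library 2 or 3.

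At day 4 the direct comparison found cell cycle genes lower and interferon-stimulated genes higher in OIS than in bypass cells. IFIT1, an antiviral gene induced by interferon (ENSG00000185745, chromosome 10, 91152303 to 91163745), was at 29.66 ± 8.18 CPM in OIS, 4.61 ± 1.43 in bypass and 14.2 in cycling cells (OIS against bypass, log2 fold change 2.68, SE 0.32, adjusted p = 1.53e-05). Of the 28 interferon genes 13 were higher and none lower (22 over the list alone, median 1.39, camera adjusted p = 4.21e-26, and 0.000992 with an estimated correlation), among them MX1 (10.29 ± 2.15 against 1.61 ± 0.807 CPM) and OAS1 (3.26 ± 0.675 against 0.331 ± 0.29). MKI67 was at 1.82 ± 0.871 CPM in OIS and 31.13 ± 10.3 in bypass (log2 fold change -4.07, SE 0.56, adjusted p = 7.87e-05). In all, 431 genes differed, 134 higher and 297 lower in OIS. With GC and length offsets 810 differed, and the share of higher calls went from 31.1% to 44.1% (357 higher).

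**Figure D4:**
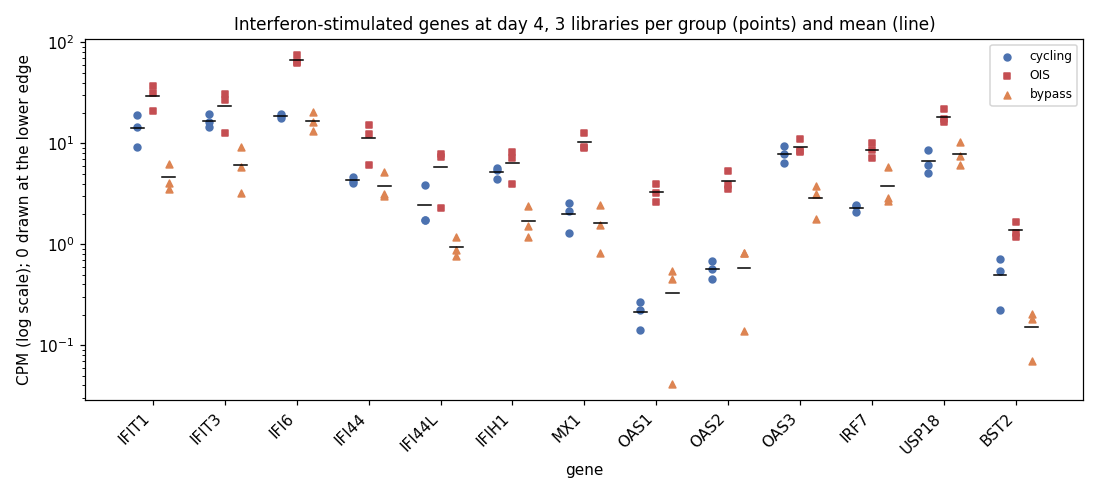
CPM (vertical axis, log scale) of the 13 interferon-stimulated genes that were higher in OIS than in bypass cells at day 4 (horizontal axis), in the 3 libraries of cycling, OIS and bypass cells at day 4 (points) with the mean of each group (line). IFIT1 averages 14.2 CPM in cycling, 29.7 in OIS and 4.61 in bypass cells.

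Replication genes (29 of 51 lower, 39 over the list alone, median -1.14) and mitosis genes (49 of 63 lower, 54 over the list alone, median -2.5) were called at day 4, also with an estimated correlation (adjusted p = 0.00351 and 0.00186). KIF2C, a mitotic kinesin, was at 0.78 ± 0.321 CPM in OIS and 14.33 ± 6.35 in bypass, and TK1 at 4.61 ± 1.66 against 32.21 ± 6.8. CDKN2B was at 242.1 ± 12.5 against 103.7 ± 5.52 CPM (adjusted p = 0.00564). Calls of SASP (6 higher, 3 lower of 66), NF-kB (0 of 23 past the threshold), contractile (4 of 27 lower), glycolysis (2 of 24 lower, 13 over the list alone), unfolded protein stress (1 of 26 lower) and neural genes (2 of 15 higher) were lost with an estimated correlation (adjusted p = 0.324, 0.229, 0.116, 0.225, 0.555 and 0.123). The NF-kB call was also lost without bypass day 4 library 3 (0.0516). The unfolded protein stress call was lost without OIS day 4 library 1 (0.11) or bypass day 4 library 1 (0.284), with GC and length offsets (0.0535) and with all libraries numbered 1 set aside (0.28). The 5 epithelial genes were called lower with the replicate number as a block (0.0346), the library letter as a covariate (0.0125) or only the compared groups in the fit (0.034), and without bypass day 4 library 3 (0.0343). IL8 was at 197.3 ± 46.9 against 61.37 ± 33.1 CPM (adjusted p = 0.129, and 0.0185 with the replicate number as a block). With no filter on low counts IL8 was called at 5.24e-09 and IL6 at 0.0441 (0.54 with the filter). BRAF, LMNB1, LMNA, CDKN1A, CDKN2A and IL1B were not called (adjusted p = 0.822, 0.144, 0.522, 0.887, 0.424 and 0.552), though CDKN2A was called with GC and length offsets (0.00801). The count of genes was 1176 (759 higher) with no filter on low counts, 1399 (951 higher) with all libraries numbered 1 set aside and 663 with DESeq2. It was 804 (497 higher), 253 and 249 without OIS day 4 library 1, 2 or 3, and 199 without bypass day 4 library 3.

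Quiescent cells were compared with cells in serum to ask what changes when proliferation stops without an oncogene. Cell cycle genes fell, genes of FOXO activity and quiescence rose, and many SASP and glycolysis genes were lower. MKI67 fell from 206.6 ± 130 to 0.868 ± 0.757 CPM (log2 fold change -7.87, SE 0.66, adjusted p = 4.62e-09), and MMP1, the interstitial collagenase, from 4585 ± 2050 to 86.76 ± 26.6 (-5.72, SE 0.33, adjusted p = 2.96e-11). GAS1, a growth arrest gene, rose from 6.18 ± 0.585 to 144 ± 3.97 CPM (4.54, SE 0.3, adjusted p = 1.1e-10). LMNB1 fell from 78.16 ± 22.2 to 5.15 ± 0.821 CPM (-3.92, SE 0.26, adjusted p = 1.36e-10), whereas LMNA was at 941.5 ± 306 against 1033 ± 123 (adjusted p = 0.658). In all, 6482 genes changed, 3472 higher and 3010 lower. The majority turned with GC and length offsets (3682 higher, 4086 lower) and without serum library 2 (2729 and 2902). The median log2 fold change of all genes was 0.098, and -0.02 with GC and length offsets.

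All 51 replication genes and 60 of the 63 mitosis genes fell, also when adjusted over the list alone (medians -2.79 and -5.76), and 28 of the 33 FOXO and quiescence genes rose (29 over the list alone, median 1.66). These calls held with an estimated correlation (adjusted p = 0.00316, 0.00316 and 0.00833). RRM2, a subunit of ribonucleotide reductase, fell from 237.9 ± 58.3 to 0.919 ± 0.495 CPM, and SPC25, a kinetochore gene at 15.38 ± 5.24 CPM in serum, was at 0 counts in quiescent cells, at least 59.7-fold lower. MXI1, a partner of MAX, rose from 10.65 ± 1.05 to 42.67 ± 3.52 CPM. ADH1B, an alcohol dehydrogenase gene, was at 38.7 ± 11.3 CPM in quiescent cells, a count ratio of 1360 (95% counting interval 244 to 53900), and GUCY1A3, a subunit of guanylate cyclase, was at least 49-fold higher than in serum, where it had 0 counts. CDKN2B rose from 6.75 ± 1.72 to 61.31 ± 10.7 CPM and CDKN2A from 22.55 ± 2.64 to 55.81 ± 27.4, and CDKN1A was at 655.3 ± 290 against 337.4 ± 56.2 (adjusted p = 0.00761, 0.0935 without quiescent library 1, and 0.125 with all libraries numbered 1 set aside).

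Of the 66 SASP genes, 30 fell and 7 rose (33 and 7 over the list alone, median -1.24, camera adjusted p = 3.04e-06), and of the 24 glycolysis genes 20 fell, also over the list alone (median -1.34, camera adjusted p = 2.28e-09). Of the 49 ribosome biogenesis genes 30 fell (36 over the list alone, median -0.79, camera adjusted p = 2.46e-08). These 3 calls were lost with an estimated correlation (adjusted p = 0.175, 0.158 and 0.0948). IL8 fell from 53.54 ± 39.5 to 1.05 ± 0.207 CPM, IL6 from 17.2 ± 14.5 to 0.938 ± 0.496, PFKP, a phosphofructokinase gene, from 529.1 ± 19.1 to 59.21 ± 19.5, and DKC1 (dyskerin) from 101.1 ± 8.51 to 40.38 ± 5.44. Of the 28 interferon genes 17 rose and 1 fell (18 and 1 over the list alone, median 1.6, and 0.0948 with an estimated correlation), with IFIT1 at 47.52 ± 11 against 3.32 ± 1.03 CPM. Of the 49 matrix genes 23 rose and 6 fell (25 and 6 over the list alone, median 0.65, and 0.638 with an estimated correlation), with FBLN1 (fibulin 1) at 877.6 ± 167 against 162.1 ± 50.4 CPM. Of the contractile genes 18 fell and 2 rose, also over the list alone (median -0.8, and 0.366 with an estimated correlation), with TPM1 (tropomyosin 1) from 1860 ± 548 to 203.9 ± 39.1 CPM.

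The calls of ERK pathway (14 of 27 fell), p53 target (18 of 35 rose), nuclear lamina (12 of 31 fell) and lysosome genes (20 of 44 rose) in quiescent cells were lost with an estimated correlation (adjusted p = 0.419, 0.096, 0.121 and 0.64). Against these directions, 3 ERK pathway and 3 nuclear lamina genes rose, and 4 p53 targets and 4 lysosome genes fell. The lamina call was also lost without quiescent library 1 (adjusted p = 0.059). The lysosome call was lost without quiescent library 1 (0.14), serum library 1 (0.115) or serum library 2 (0.073). Both were lost with only the compared groups in the fit (0.0644 and 0.0884) and with all libraries numbered 1 set aside (0.0888 and 0.356). Cholesterol synthesis (6 rose, 2 fell of 29), unfolded protein stress (10 rose, 2 fell of 26), heat shock (5 of 13 fell), epithelial (1 rose, 3 fell of 5), endothelial (2 rose, 2 fell of 7), blood cell (1 rose, 1 fell of 3) and neural genes (7 rose, 3 fell of 15) were not called (camera adjusted p = 0.995, 0.19, 0.124, 0.604, 0.628, 0.628 and 0.628). Heat shock genes were called lower with no filter on low counts (0.00576). Heterochromatin genes (8 rose, 14 fell of 46, camera adjusted p = 0.059) were called lower with the replicate number as a block (0.0407), no filter on low counts (0.00398) or GC and length offsets (0.0319), and without serum library 1 (0.0369), serum library 3 (0.0339) or quiescent library 3 (0.0478). NF-kB targets (2 rose, 11 fell of 23, camera adjusted p = 0.0643) were called lower without serum library 1 (0.0383), with no filter (0.000893) and with all libraries numbered 1 set aside (0.023). With those libraries set aside the cholesterol synthesis list was called lower (median -0.457, adjusted p = 0.0491).

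The OIS effect at day 10 was set against the quiescence effect to ask which changes belong to arrest in general. Replication and mitosis genes fell in both, and SASP genes moved apart. Of the 66 SASP genes, 49 had a higher effect in OIS and 5 a lower one (52 and 5 over the list alone, median difference 4.52, camera adjusted p = 1.67e-29, and 0.00351 with an estimated correlation), and of the 27 ERK pathway genes 21 had a higher and 2 a lower one (23 and 2 over the list alone, median 2.15, adjusted p = 0.00972 with an estimated correlation). The metalloproteinase gene MMP3 was at 1935 ± 596 CPM in OIS and 1.76 ± 0.715 in cycling cells, against 0.438 ± 0.265 in quiescent and 41.94 ± 60.1 in serum cells (difference of effects 16.65, SE 1.49). ASPN, the matrix gene asporin, was at 0.116 ± 0.0718 in OIS and 2.02 ± 0.659 in cycling cells, against 250.5 ± 139 in quiescent and 3.47 ± 3.04 in serum cells (-10.17, SE 1.01). In all, 5465 genes differed between both effects, 2774 higher and 2691 lower in OIS. Higher and lower calls were nearly even, and the majority turned with the replicate number as a block (2957 and 2967), all libraries numbered 1 set aside (3007 and 3206) or only the compared groups in the fit (2115 and 2193). It turned also without OIS day 10 library 1 (2481 and 2482), cycling day 10 library 3 (2436 and 2437), serum library 1 (2727 and 2732) or quiescent library 3 (2343 and 2358). Both experiments differ also in transduction and puromycin selection. Levels in their controls differed as well. IL6, IL8 and IL1B, the inflammatory genes among those always named, were at 17.2 ± 14.5, 53.54 ± 39.5 and 12.46 ± 13.6 CPM in serum cells. In cycling cells at day 10 they were at 1.36 ± 0.352, 0.514 ± 0.175 and 1.91 ± 0.986. These controls were not tested against each other. A difference of effects contains the control levels, so part of it may come from the controls for such genes.

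Further list differences between both effects were lost with an estimated correlation: higher in OIS for replication, mitosis, NF-kB, ribosome biogenesis and glycolysis genes (medians 0.67, 1.22, 1.15, 0.79 and 0.96, adjusted p = 0.419, 0.595, 0.0584, 0.265 and 0.572) and lower for interferon, matrix, contractile and FOXO genes (medians -2.24, -1.93, -1.25 and -0.74, adjusted p = 0.164, 0.155, 0.196 and 0.206). Of the genes called in OIS at day 10 and in quiescence, 917 rose in both, 1005 fell in both and 1000 moved in opposite directions, against 740.6, 558.2 and 1285.9 from independent lists of these sizes. Across genes, the Pearson correlation of both effects was 0.183 and Spearman's rho 0.151. These 2 effects share no library.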

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

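The test of the difference between the OIS effects at days 10 and 4, planned before the data were examined, called 1037 genes, and the results here are those it called. In 5 of 100 drawn regroupings of the libraries, the real one included, as many genes were called, and the highest other called 1400, so by the share set before the data were examined (0.05) chance is not excluded for this count. The 4 others kept the OIS libraries of each day together and exchanged cycling libraries only, so that the real difference between OIS libraries remained in them, which was noticed after the counts were seen. In all, 12 others kept the OIS libraries of each day together, and these 4 are among them. Of the other regroupings, 78 mixed both OIS and cycling libraries between days, and the highest of these, singled out after the counts were seen, called 1. Such mixing adds any real difference between days to the spread within groups and lowers the count, so that value cannot exclude chance. The count was 632 without cycling day 4 library 2 and 2281 with GC and length offsets, an alternative chosen after the data were seen.

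Of 9 lists called in this test, extracellular matrix (median difference -1.29, camera adjusted p = 7.02e-23) and contractile genes (-1.33, adjusted p = 4.92e-24) were called also with an estimated correlation. The interferon response (-0.76, adjusted p = 6.04e-06) and p53 targets (0.42, adjusted p = 0.000335) had adjusted p = 0.0594 and 0.0768 with an estimated correlation. The others were DNA replication (-0.31, adjusted p = 0.00261), mitosis (-0.32, 0.03), lysosome (0.25, 0.0108), FOXO (0.57, 0.0281) and glycolysis genes (-0.3, 0.033), with adjusted p of 0.572, 0.777, 0.572, 0.422 and 0.677 with an estimated correlation. The replication call was lost with all libraries numbered 1 set aside (0.165). The mitosis call was lost without OIS day 10 library 1 (0.105) or 2 (0.0517), cycling day 4 library 2 (0.23), OIS day 4 library 2 (0.0538) or 3 (0.114), or cycling day 10 library 3 (0.0704). The FOXO call was lost without cycling day 4 library 1 (0.0563), OIS day 4 library 1 (0.0725), OIS day 10 library 2 (0.0886) or cycling day 10 library 3 (0.139). The glycolysis call was lost without cycling day 4 library 1 (0.0985) or 2 (0.11), OIS day 4 library 1 (0.0667) or 3 (0.0666), cycling day 10 library 1 (0.0964) or OIS day 10 library 2 (0.219), with the library letter as a covariate (0.0631) and with all libraries numbered 1 set aside (0.0989).

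The genes considered here were named for OIS against cycling cells at either day or for the difference between days. Of those reported, 34 differed between the days, 13 higher and 21 lower at day 10. Some were named because they passed this same test, so the count does not measure how often named genes differ. Over all 14210 tested genes, 7.3% differed. Each difference also contains the levels of the cycling cells at both days. The log2 differences above 0 were LONRF3 11.58, MUM1L1 10.71, HAVCR2 7.77, DUSP4 7.07, BMP2 4.68, IL8 3.74, IL1B 3.36, CTSS 3.3, SYP 3.21, GDF15 2.18, CDKN2B 1.94, CDKN1A 1.68 and YPEL2 1.44. Those below 0 were POLR1E -1.33, LMNB1 -1.35, FLNC -1.38, GAS6 -1.51, TK1 -1.91, PDK1 -2.05, COL1A2 -2.49, MUC1 -2.69, GAS1 -3.03, KRT19 -3.13, CYR61 -3.49, OAS1 -3.58, OXTR -4.08, CD4 -4.34, EFEMP1 -4.39, CLDN11 -4.51, PSG5 -4.58, ENPP2 -4.91, ABI3BP -7.11, MMP25 -7.11 and ANO3 -9.58. Fitted differences of genes with groups at or near 0 counts (LONRF3, MUM1L1, HAVCR2, MMP25 and ANO3) depend on the prior count and are no bounds. LONRF3 lost its call without cycling day 4 library 2 (adjusted p = 1), cycling day 10 library 1 (0.0523), 2 (0.0569) or 3 (0.0526), OIS day 10 library 1 (0.0566), or OIS day 4 library 2 (0.0501) or 3 (0.057), with the library letter as a covariate (0.051) and with only the compared groups in the fit (0.0533). MUM1L1 lost it without cycling day 4 library 1 (0.0677) or 3 (0.0691), HAVCR2 without cycling day 4 library 2 (0.24) and ANO3 without cycling day 10 library 3 (0.132). With all libraries numbered 1 set aside, DUSP4 (0.0592), LONRF3 (0.0513) and MUM1L1 (0.131) lost theirs.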

How the results depend on the processing

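The GC and length offsets and the setting aside of all libraries numbered 1 were chosen after the data were seen, and the other alternatives before. Genes that differed between OIS and bypass cells at day 4 numbered 431, and 1176 with no filter on low counts, 810 with GC and length offsets, 1399 with all libraries numbered 1 set aside and 663 with DESeq2. Between OIS and bypass cells at day 10 there were 1524, and 529 with only the compared groups in the fit and 2520 with the offsets. The offsets gave 4424 in place of 2912 for OIS at day 4, and 2281 in place of 1037 for the difference between days. With only the compared groups, bypass against cycling cells at day 4 gave 5022 in place of 2730. The cause of these changes was not tested. Cholesterol synthesis genes in quiescence reversed, from a median of 0.27, not called, to -0.457 (adjusted p = 0.0491) with all libraries numbered 1 set aside. Every other count stayed within 1.5 times its main value under the alternatives that leave out no single library.

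Leaving out 1 library at a time, counts ranged from 4743 to 5795 (OIS day 10), 2120 to 2591 (OIS day 4), 3201 to 3486 (bypass day 10), 1340 to 1936 (bypass day 4), 781 to 2449 (OIS against bypass, day 10), 199 to 804 (the same, day 4) and 5357 to 6755 (quiescence). They ranged from 632 to 1295 for the difference between days and 4701 to 6257 for the difference from quiescence. Calls shared in direction were 1650 to 1929 for OIS and quiescence and 2674 to 3489 for OIS and bypass. The lowest and highest came without bypass day 4 library 1 (1340), bypass day 10 library 3 (781), OIS day 10 library 2 (2449), bypass day 4 library 3 (199), OIS day 4 library 1 (804) and cycling day 4 library 2 (632).

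In what follows, a result that stayed lay on the same side of the threshold as in the main fit, whether called or not. Over fits that leave out 1 library, 2550 results of named genes stayed, 158 calls were lost and 4 gained. Of list results 1435 stayed, 52 calls were lost and 31 gained. With the replicate number as a block 432 gene results and 200 list results stayed. The block lost 2 gene calls and 3 list calls, gained 2 and 4, and moved no count by over 1.5 times. Of its list calls not named above, it gained unfolded protein stress genes in the difference from quiescence (adjusted p = 0.0464) and epithelial genes in bypass cells at day 4 (0.0476). It changed no call other than these, those given beside their results, and those of LGMN (0.0503) and ARSB (0.0547), lost. With RLE factors 435 gene results and all 207 list results stayed, and 1 gene call was lost. With the estimated correlation 146 list results stayed, including every list called with neither correlation, and 61 calls were lost. With no filter on low counts 419 gene results stayed, 10 calls were lost and 7 gained, and of list results 193 stayed, 1 call was lost and 13 gained. With only the compared groups these were 407, 24 and 2 for genes and 199, 5 and 3 for lists, and with the library letter 430, 5 and 1 and 199, 5 and 3. With the offsets they were 426, 7 and 3 and 198, 6 and 3, and with all libraries numbered 1 set aside 420, 14 and 2 and 188, 8 and 10, besides the reversed one. With DESeq2 433 gene results stayed, 2 calls were lost and 1 was gained.

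List calls gained under alternatives that leave out no single library, where not given beside their results, were as follows, with adjusted p. Matrix and FOXO genes were called with no filter in OIS (0.0426 and 0.02) and bypass cells at day 4 (0.0426 and 0.0114), and with all libraries numbered 1 set aside (0.00683 and 0.0413, and 0.00603 and 0.0115). FOXO genes in bypass cells at day 4 were called also with the offsets (0.0353). In bypass cells at day 10, cholesterol synthesis (0.0166), lysosome (0.0345) and glycolysis genes (0.017) were called with no filter, the first also with only the compared groups (0.0406). Glycolysis genes were called between OIS and bypass cells at day 10 with no filter (0.0363), the offsets (0.0409) and those libraries set aside (0.0137). Cholesterol synthesis genes were called between OIS and bypass cells at day 4 with only the compared groups (0.0171) and those libraries set aside (0.0121). Epithelial genes were called in bypass cells at day 4 with the library letter (0.034). In the difference from quiescence, heat shock genes were called with no filter (0.0118) and unfolded protein stress genes with the library letter (0.0497) and those libraries set aside (0.0243), as were neural genes in the difference between days with those libraries set aside (0.00979). The cause of these changes was not tested.

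In simulated data, 38% of 2-fold changes were recovered for OIS at day 10 and 48% for quiescence, so there a gene that did not pass the test can have changed by that much. The simulations held fewer changed genes, with 127 and 126 calls against 5666 and 6482 in the real comparisons. Benjamini-Hochberg adjustment is stricter with fewer calls, so these shares are not those of the real tests. The other comparisons were not simulated.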

Other observations

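The values of some gene families, chosen after they were seen, are given here without a test against other genes. Near-identical members make these counts uncertain. The 6 measured pregnancy-specific glycoprotein genes on chromosome 19 (43370616 to 43711451) all fell in OIS at day 10 (median log2 fold change -5.65) and in quiescence (-4.9), and 5 of them were lower in OIS than in bypass cells at day 10. Of 6 matrix metalloproteinase genes on chromosome 11 (102582526 to 102826463), 4 rose in OIS and 6 in bypass cells at day 10, while 3 fell in quiescence. Of 7 chemokine genes on chromosome 4 (74606223 to 74965010), 6 rose in OIS and 7 in bypass cells at day 10, and 3 fell in quiescence. MMP1, the interstitial collagenase, was at 18670 ± 2460 CPM in OIS at day 10 and 2827 ± 311 in cycling cells. CXCL5, a chemokine gene, was at 289.9 ± 99.9 against 0.6175 ± 0.0075 CPM.

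Of 17 measured histone genes, 6 rose in OIS at day 10, 7 rose in quiescence and 8 were higher in OIS than in bypass cells at day 10, while none passed the test in OIS at day 4 (1 fell with GC and length offsets), and in bypass cells 1 rose and 1 fell at day 10 and 3 fell at day 4 (4 with offsets). No family direction given here flipped with those offsets. HIST1H2BD was at 41.27 ± 5.45 CPM in OIS at day 10, 5.674 ± 1.59 in cycling and 13.47 ± 3.37 in bypass cells. Late cornified envelope genes on chromosome 1 (152670840 to 152770657) rose in bypass cells (3 of 3) and in OIS (2 of 3) at day 10. The other one, LCE2A, was at 48.6 ± 13.7 CPM in bypass cells against 1.904 ± 0.155 in OIS and 1.274 ± 0.367 in cycling cells. TERT, which the cells carried as an introduced gene, was lower in quiescent than in serum cells, at 196.3 ± 24.1 against 821.4 ± 244 CPM (log2 fold change -2.06).

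Of the tests that follow, those of the axis, of the interferon genes and of gene-poor regions were chosen only after the result was seen, whereas the regroupings were planned before. Within groups, libraries deviated along 1 axis, holding 40% of the within-group variance, of long AT-rich against short genes. Removing each library's trend on GC content and length lowered the summed squared scores by 83.2%. Since GC content and length had served to describe the axis, this fall restates it, and a bias of the libraries and a real change of such genes cannot be told apart by it. Same-numbered libraries of the transduction experiment scored alike (exact permutation p = 0.00643 over 7776 arrangements, one-sided), as did those that carry the same date in their column names (0.0262 over 46656 arrangements). A shared round or day may thus contribute there, and these tests do not separate both. In the serum experiment the sum of products of same-numbered scores was -2267 over 3 pairs, whose 6 arrangements are too few to decide. No biological explanation was tested.

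Interferon-stimulated genes were higher in OIS than in bypass cells at day 4. A share of cycling cells among the bypass cells would remove the same part of every OIS rise. The median missing part was 99.3% over 15 interferon genes that rose in OIS (quartiles 91.9 and 107.1). It was 32.7% over 1691 other genes that rose (one-sided permutation p = 1e-05, the smallest that the draws can give). The list was singled out because it was higher in OIS than in bypass cells in these libraries, which favours a large missing part. The draws also treat genes as independent, so this test cannot decide whether cycling cells contribute. This test replaced a first one, in which 5 of the 13 genes were lower in bypass than in cycling cells, 0 higher and 8 not called (median -0.32). Neither a GC and length bias (adjusted p = 5.58e-29 with offsets) nor a single library (highest adjusted p = 1.82e-22 over 6 fits that leave out 1) accounts for the call. An effect of the small T antigen stays open and untested.

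Fold changes varied with the number of protein-coding neighbours of a gene, with a mean absolute Spearman correlation over genes of 0.143 in the 7 comparisons, where genes are not independent replicates. It was 0.035 with GC and length offsets, a fall of 75.3%, which is consistent with a GC and length bias for most of it. With offsets, correlations of -0.044 (OIS day 4), 0.057 and -0.054 (OIS against bypass, days 10 and 4) still lay outside the range of 1000 circular shifts along the genome (permutation p = 0.001, the smallest they can give), and that of quiescence was -0.038 (0.002). The offsets may also remove real signal, since gene density and GC content go together. The hypothesis that tested genes in gene-poor regions rise as a whole in OIS at day 10 needs a correlation below 0. It was 0.107, and 0.029 with offsets (permutation p = 0.016). A rise of only some of these genes, or of genes removed by the filter, was not tested. The prediction for the offsets was written before the corrected values were seen, when those without offsets had been seen.

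Regrouping 3 libraries against 3 gives 10 splits, too few for a share under 0.05. The real split was the 1 with the most calls in each of the 7 comparisons. Every other split mixes libraries of both groups, which adds any real difference between them to the spread within groups and lowers the count. Low counts in those splits thus cannot exclude chance. The real and highest other counts were 5666 and 0 (OIS day 10), 2912 and 0 (OIS day 4), 4074 and 0 (bypass day 10), 2730 and 0 (bypass day 4), 1524 and 4 (OIS against bypass, day 10), 431 and 0 (the same, day 4) and 6482 and 2 (quiescence). Of the 4 splits that part all 3 same-numbered pairs, those other than the real one called 0 genes, except 2 in quiescence. For the difference between the OIS and quiescence effects, 1 of 100 drawn regroupings, the real one, called as many as 5465 genes. The highest other called 4663. That share lies below the 0.05 set beforehand, but it cannot exclude chance here. Regroupings that mix OIS with quiescent libraries put unlike cells into 1 group, which lowers their counts. The 8 others that kept these apart called 3415 to 4663, and 8 are too few for a share under 0.05. The highest of the 78 that mixed libraries in both exchanges called 2678. Of the 431 genes that differed between OIS and bypass cells at day 4, 30 were also called higher in bypass than in cycling cells and highest in bypass of the 3 groups, and 15 were lowest there by the same tests. At day 10 these were 116 and 91 of 1524.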
